A study of Mus musculus with 11 samples.

How the data were processed

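Single-cell RNA sequencing was carried out on CD45+ cells sorted from the dissociated cortices of perfused 5-month-old mice, in 11 libraries made with a droplet-based 3′ gene expression kit. The labels name 4 genotypes: Atg7-fl/fl (WT, n = 3), Atg7-fl/fl with Cx3cr1-CreERT2 (KO, n = 3), Atg7-fl/fl with the 5xFAD transgenes (5xFAD_WT, n = 2) and Atg7-fl/fl with both (5xFAD_KO, n = 3). They call the samples biological replicates, name no batch and do not say how or when the Cre recombinase was activated. They also do not say that each library came from a separate animal, so the p-values of single genes and of shares measure the spread between these libraries.

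The deposited matrices hold raw UMI counts per gene and cell barcode, which the authors made with Cell Ranger 6.0.1 against the GRCm39 genome, per the submitters' processing notes and the matrix headers. The same notes also list Seurat 4.0 and R 4.1.0 without a role. All libraries share 21835 features with Ensembl identifiers. No barcode held fewer than 500 UMIs, and the cell filter behind the 96376 barcodes is otherwise not stated. The gene annotation at hand was built for an earlier mouse assembly than the one named in the notes, so no coordinates are given. Xist was not among the features, and the alternative that would have used it as a covariate was not run.

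Barcodes with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs were kept, which left 93316. Scrublet, as implemented in scanpy 1.11.5, scored doublets in each library. Its automatic threshold failed in several libraries, so a common score of 0.25 was used in all, which removed 5011 barcodes and left 88305. After normalisation and log transformation, 2000 variable genes, 30 principal components and 15 neighbours went into Leiden clustering (leidenalg 0.10.2, igraph 0.11.9, resolution 1.0), giving 36 clusters. A cluster took the name of the marker list with the highest score, and the limits of that naming step were set after the clusters had been seen. The 9 microglia-like clusters held 51041 cells, 10 clusters stayed unnamed, and the unnamed share was between 6.47% and 11.7% in every library.

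UMI counts of the microglia-like cells were summed per library and tested with edgeR 4.0.16 in R 4.3.3 (TMM normalisation, filterByExpr, quasi-likelihood F test, two-sided, 11707 genes, Benjamini-Hochberg adjusted p under 0.05). A single model with 1 mean per group over all 11 libraries gave the 4 pairwise comparisons and the interaction, which tests whether the Cre genotype acts differently with and without 5xFAD. The mean of the 2 Cre contrasts and the mean of the 2 5xFAD contrasts were added after the single comparisons had been seen. Log2 fold changes are given with a standard error (SE) computed as the absolute log2 fold change over the square root of its F statistic. Expression levels are given as CPM, counts scaled to 1e6 of the TMM-adjusted library total, with the SD between libraries. Esr1, Cx3cr1 and S100a8 levels compared between cell classes or clusters are scaled to the plain UMI total instead. Fold changes of sums describe the average cell and cannot separate a shift in cell states from a shift within each cell.

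Gene lists (25) and marker lists of other cell types (13) were fixed before the data were examined, as were the groups, tests and most alternatives. Some lists share members, so their results are not independent. Ferroptosis defence shares Slc7a11, Gclc, Gclm, Gsr, Txnrd1 and Nqo1 with the NRF2 target list, and Fth1, Ftl1 and Slc40a1 with iron handling. Iron handling shares Hmox1 and Blvrb with the NRF2 list. Lipid handling shares Apoe, Lpl, Fabp5 and Ch25h with the list of disease-associated microglia. Camera (limma 3.58.1) tested each list against all other genes with a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 25 lists of a comparison. Camera with a correlation estimated from the libraries was run beside it, as was fry, which tests whether the genes of a list move one way on balance without comparing them with other genes. At the preset correlation a camera p-value sets the genes of a list against other genes. It does not measure how well a list result repeats between libraries. Member counts are given over all genes tested and adjusted over the list alone.

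The named genes followed a rule fixed at the same time. Atg7 came first. Each comparison then took up to 8 genes with the largest positive and 8 with the largest negative log2 fold change among genes past 0.05, with a mean of at least 20 CPM and no overlap between the libraries compared. For the interaction the rule took the 5 smallest p-values in each direction among genes past 0.05. Up to 3 members with the smallest p came from each list that passed or held a changed gene. Sqstm1, Hspa5, Atf4, Ddit3, Gpx4, Slc7a11, Fth1, Apoe, P2ry12 and Trem2 were named in every pairwise comparison, and members of lists summarised by counts could be left out. A gene named outside this rule is said to be so.

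The share of microglia-like cells and the share of disease-associated microglia (DAM) were compared with an exact permutation test, two-sided, on the mean of the within-stratum differences. All 200 arrangements of the library labels within strata were enumerated, so the smallest possible p is 0.005. For the DAM share, each microglia-like cell was thinned to 2000 UMIs, and a cell counted as DAM-high when its UMIs from the DAM list exceeded the 95th percentile of WT cells, averaged over the WT libraries. Shallower cells were left out, between 5.97% and 35.3% of a library.

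The libraries fell into 2 sets that no label names. They were defined from the first principal component of the T cell-like cells, after the data had been examined and after models with other indicators had been tried. The set was then used as a covariate in every comparison, and the shares were permuted within sets (24 arrangements, smallest possible p 0.0417). Replicate numbers were tested as pairs and did not pair the libraries, with correlations between -0.412 and 0.394 over 15 pairs of the same number.

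Alternatives comprised DESeq2 1.42.0, DESeq2-style size factors (RLE) in edgeR, no filter on low counts, a stricter cell filter (2000 UMIs, 5% mitochondrial UMIs), doublets kept, Leiden resolution 0.5, all cells summed, libraries thinned to the smallest, a replicate block, only the compared groups, and each library left out in turn. Chosen after the data had been seen were the library set, the neutrophil marker level as a covariate, and leaving out KO replicate 1 with 5xFAD_WT replicate 2.

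The pipeline was tested on simulated data with the depth and spread of these libraries. For KO against WT it recovered 17.9% of genes changed 1.5-fold, 64.2% of those changed 2-fold and 86.4% of those changed 4-fold. A list lowered 1.4-fold passed camera, and 0 of the other lists did. The simulated genes varied independently of each other, so camera was not tested where the genes of a list vary together. Permutations used 100000 resamples where enumeration was too long, and Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 did the rest.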

Results

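Gene expression was measured in 11 single-cell libraries from mouse cortex, as counts of unique molecular identifiers (UMIs) for 96376 cell barcodes, of which 88305 were kept. Cells carrying the leukocyte antigen CD45 had been sorted, so microglia and blood-derived leukocytes were both present. Atg7 encodes an enzyme needed to lipidate LC3 and form autophagosomes. Mice homozygous for floxed Atg7 were the control group (WT, n = 3), and the same genotype with the microglia and macrophage driver Cx3cr1-CreERT2 gave the knockout group (KO, n = 3). The 5xFAD transgenes, which drive amyloid plaque formation, were added to each (5xFAD_WT, n = 2; 5xFAD_KO, n = 3). The series title names loss of ATG7 in microglia, the unfolded protein response (UPR), ferroptosis and amyloid, and the comparisons address how the Cre genotype changes microglia in plaque-free and plaque-bearing cortex. The WT libraries held 47900500, 36235489 and 12719324 UMIs for replicates 1, 2 and 3. The KO libraries held 45826491, 16696392 and 20451696 UMIs. The 5xFAD_WT libraries held 47039145 and 70647846 UMIs, and the 5xFAD_KO libraries 32014636, 26936697 and 23074071. The 51041 microglia-like cells gave between 7499015 and 23896716 UMIs per library once summed.

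The libraries fell into 2 sets that no label names. On the first principal component of the T cell-like cells, which took 33% of the variance over 3982 genes, 5 libraries lay between -9.34 and -6.97 and the other 6 between 6.39 and 7.81. WT replicates 1 and 2, 5xFAD_WT replicate 1 and 5xFAD_KO replicates 1 and 2 formed set 1. WT replicate 3, all 3 KO libraries, 5xFAD_WT replicate 2 and 5xFAD_KO replicate 3 formed set 2. The median UMI count of microglia-like cells was 2961.5 to 3438 in set 1 and 2226 to 2746 in set 2. With genotype in the model, 3913 genes of the microglia-like sums differed between the sets, 2058 higher and 1855 lower in set 2. In T cell-like sums 579 genes differed, and the set effects in both classes had a Pearson correlation of 0.810 across 3198 genes, which are not independent replicates. Because every KO library was in set 2, KO against WT within a set rested on WT replicate 3 alone, and 5xFAD_KO against KO on 5xFAD_KO replicate 3 alone. Each comparison is therefore given without and with the set as a covariate, and 5xFAD_KO against 5xFAD_WT and 5xFAD_WT against WT had both sets in both groups.

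**Figure D1:**
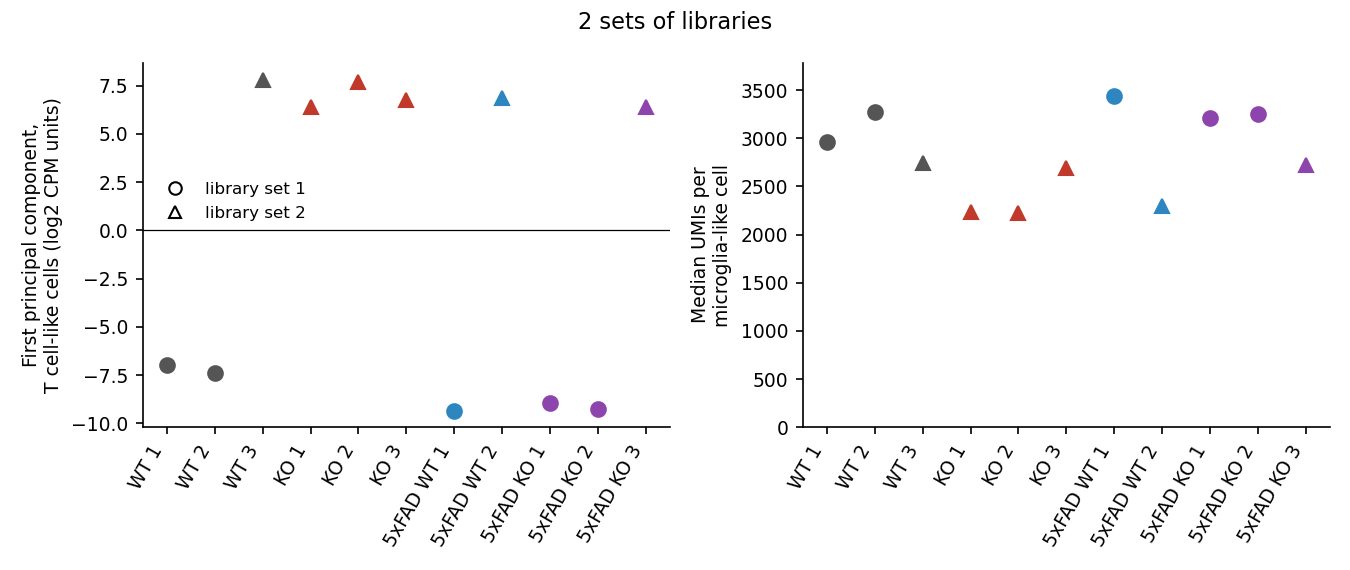
The left panel plots the first principal component of T cell-like cells and the right panel the median UMI count of microglia-like cells, with 1 point per library in each genotype group. The 5 libraries of set 1 sit between -9.34 and -6.97 on the component and at or above 2961.5 UMIs per cell, and the 6 of set 2 between 6.39 and 7.81 and at or below 2746 UMIs.

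The first question was whether Atg7 messenger RNA was lower where the Cre driver was present. Atg7 (ENSMUSG00000030314) was at 30.7 ± 4.02 CPM in WT (SD, n = 3) and 29.3 ± 3.08 in KO (SD, n = 3), a log2 fold change of -0.06 ± 0.22 (adjusted p = 0.928). In the 5xFAD background it was at 31.1 ± 10.6 CPM in 5xFAD_WT (SD, n = 2) and 21.7 ± 6.26 in 5xFAD_KO (SD, n = 3), a log2 fold change of -0.51 ± 0.24 (adjusted p = 0.595). The mean of both Cre contrasts was -0.29 ± 0.16 (adjusted p = 0.528). With the library set as a covariate it was -0.42 ± 0.09 (adjusted p = 0.0223), and the pairwise Atg7 values were -0.43 (adjusted p = 0.170) and -0.42 (adjusted p = 0.166). Without WT replicate 3 or KO replicate 3 the KO against WT value for Atg7 was 0.05 or 0.02. The reads are 3′ tags, which count transcripts whether or not an internal exon has been removed, so recombination and protein loss were not measured. Each Cre library also carried the driver in the Cx3cr1 gene and each library without Cre lacked it, so loss of Atg7 was not separable from the driver.

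In plaque-free cortex, KO against WT asked what the Cre genotype alone did to microglia. Among genes that passed, the largest rise was in the estrogen receptor gene Esr1 (ENSMUSG00000019768). Its level went from 2.89 ± 0.341 CPM (SD, n = 3) to 94.1 ± 36.7 (SD, n = 3), a log2 fold change of 5.04 ± 0.31 (adjusted p = 2.58e-05). CreERT2 also contains an estrogen receptor ligand-binding domain. Pla2g7 (ENSMUSG00000023913), which encodes a phospholipase that clears oxidised phospholipids, rose from 2.98 ± 0.560 to 21.1 ± 0.855 CPM (SD), a log2 fold change of 2.80 ± 0.28 (adjusted p = 0.00322). Antioxidant and detoxifying genes rose with them, including the heme-pathway reductase Blvrb (log2 fold change 1.33 ± 0.18, adjusted p = 0.0182), the glutathione transferase Gstm1 (1.55 ± 0.24, adjusted p = 0.0373), thioredoxin Txn1 (0.61 ± 0.10, adjusted p = 0.0433) and the oxidative stress gene Osgin1 (1.56 ± 0.24, adjusted p = 0.0373). Gstm1 has close paralogs, and 3′ reads can be shared among them. The inflammatory gene Tnfaip2 (2.31 ± 0.27), Tmem205 (1.48 ± 0.21) and B430306N03Rik (1.35 ± 0.15) rose as well (adjusted p = 0.00659, 0.0219 and 0.00517). Genes that fell included the stannin gene Snn (-0.67 ± 0.10, adjusted p = 0.0262), the translocon-associated Tram1 (-0.73 ± 0.12, adjusted p = 0.0493), Tpbgl (-0.99 ± 0.17, adjusted p = 0.0493), the scaffold gene Cask (-0.59 ± 0.10, adjusted p = 0.0469) and the nuclear envelope gene Nrm (-0.57 ± 0.09, adjusted p = 0.0469).

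In all, 20 of 11707 genes passed for KO against WT, 14 higher and 6 lower, with 1292 genes at an unadjusted p under 0.05. With the set as a covariate 19 passed, 14 higher and 5 lower, of which 11 were shared. Esr1 (log2 fold change 5.23), Pla2g7 (2.29) and Blvrb (1.38) kept their calls, Osgin1, Tpbgl, Tram1 and Cask, at 1.63 ± 0.29, -0.75 ± 0.13, -0.58 ± 0.10 and -0.57 ± 0.10, lost theirs (adjusted p = 0.0694, 0.0603, 0.0694 and 0.0583), and Cx3cr1 gained one (-1.10, adjusted p = 0.00393, against -0.75 and 0.249 without the set). The count was 5 without WT replicate 1, 5 without WT replicate 2, 8 without WT replicate 3, 5 without KO replicate 2, 6 without KO replicate 3 and 9 without 5xFAD_KO replicate 1. Esr1, Pla2g7 and B430306N03Rik passed with each library left out, and the other named calls did not. DESeq2 called 135 genes. None of the fixed genes passed. The log2 fold changes were 0.42 for Sqstm1 (adjusted p = 0.363), -1.08 for Hspa5 (adjusted p = 0.333), -0.43 for Atf4 (adjusted p = 0.262), -0.22 for Ddit3 (adjusted p = 0.672), 0.02 for Gpx4 (adjusted p = 0.971) and 0.33 for Slc7a11 (adjusted p = 0.763). They were 0.40 for Fth1 (adjusted p = 0.507), 0.34 for Apoe (adjusted p = 0.757), -0.43 for P2ry12 (adjusted p = 0.349) and -0.08 for Trem2 (adjusted p = 0.870). Gpx4 was at -0.06 without WT replicate 3 and -0.00835 without KO replicate 3, and with the set Ddit3, Slc7a11 and Trem2 changed sign to 0.08, -0.17 and 0.13.

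Among the gene lists, targets of the oxidative stress factor NRF2 rose in KO against WT (24 genes, median log2 fold change 0.49, camera adjusted p = 1.90e-16; adjusted p = 0.0383 with an estimated correlation). Over all genes 4 members were called, and 10 rose adjusted over the list alone. The UPR list, whose products fold and export proteins in the endoplasmic reticulum, was lower (33 genes, median -0.47, camera adjusted p = 9.11e-20; adjusted p = 0.234 with an estimated correlation). None of its members passed over all genes and 20 fell adjusted over the list alone, with Xbp1 at -1.001 (adjusted p = 0.141), Pdia4 at -0.85 (adjusted p = 0.216) and Canx at -0.47 (adjusted p = 0.205). Homeostatic microglia genes were lower too (31 genes, median -0.36, camera adjusted p = 1.37e-11; adjusted p = 0.0383 with an estimated correlation), with Csf1r at -0.54 (adjusted p = 0.216) and 7 members lower adjusted over the list alone. This list includes Cx3cr1, whose locus carries the driver. Cluster c1 held 25.9% of microglia-like cells in WT and 9.32% in KO, and cluster c0 26.5% and 26.7%. Both had P2ry12 and Tmem119 among their leading genes, and a shift in clusters was not tested for this list. The cell cycle (5.22e-07), senescence (0.00153), inflammatory (0.0063), integrated stress response (0.0123, lower), MHC class I (0.0141) and interferon (0.0263) lists passed camera, at adjusted p = 0.530, 0.336, 0.378, 0.530, 0.741 and 0.741 with an estimated correlation. The 16 lists that did not pass included ferroptosis defence (0.221), ferroptosis drivers (0.661), iron handling (0.0887), autophagy machinery (0.761), autophagy receptors (0.379), lysosome (0.184), DAM (0.068) and TGF-beta (0.428), as camera adjusted p. The others were proteasome (0.661), MHC class II (0.264), dissociation (0.249), glycolysis (0.379), oxidative phosphorylation (0.241), cholesterol (0.064), lipid handling (0.0887) and phagocytic receptors (0.241). In no comparison did a list that passed differ in sign between its median, mean and test. Among those that did not pass here, ferroptosis drivers had a median of 0.02 and autophagy receptors one of -0.01 against camera directions of down and up, and phagocytic receptors a mean of 0.06 against a direction of down. With the set 18 lists passed. NRF2 held (adjusted p = 0.0437 with an estimated correlation), and the UPR list had a median of -0.35 (camera adjusted p = 4.52e-10; adjusted p = 0.268 with an estimated correlation). The integrated stress response no longer passed with the set (0.790), and ferroptosis defence did (0.00432; adjusted p = 0.0879 with an estimated correlation). Marker lists of T cells, NK cells, monocytes, neurons and erythroid cells were also higher in the KO sums (camera adjusted p = 0.000527, 0.00423, 0.00375, 0.00319 and 0.00544), none with an estimated correlation (adjusted p between 0.123 and 0.566).

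With amyloid present, 5xFAD_KO against 5xFAD_WT asked for the Cre effect in plaque-bearing cortex, where 5xFAD_WT had 2 libraries. Esr1 and Pla2g7 rose again, by log2 fold changes of 5.13 ± 0.36 (adjusted p = 0.000145) and 3.34 ± 0.30 (adjusted p = 0.00112), and Pla2g7 reached 70.3 ± 21.5 CPM (SD, n = 3) from 7.01 ± 3.18 (SD, n = 2). The sulfiredoxin gene Srxn1, an NRF2 target that repairs oxidised peroxiredoxins, rose by 2.12 ± 0.23 (adjusted p = 0.00353), from 4.04 ± 0.262 to 17.6 ± 4.79 CPM (SD). Gstm1 (1.93 ± 0.27, adjusted p = 0.0139) and Blvrb (1.59 ± 0.21, adjusted p = 0.00883) rose again, Blvrb from 89.6 ± 4.24 to 270.1 ± 40.3 CPM (SD). The cell cycle inhibitor Cdkn1a (1.78 ± 0.28, adjusted p = 0.0435), the ubiquitin ligase Rnf128 (1.10 ± 0.14, adjusted p = 0.00868) and B430306N03Rik (1.47 ± 0.17, adjusted p = 0.00399) completed the named calls.

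The 5xFAD_KO against 5xFAD_WT count was 14, all higher, with 991 genes at an unadjusted p under 0.05, and 79 with the set as a covariate, 44 higher and 35 lower, which included all 14. Calls gained with the set were the glutathione synthesis gene Gclm (1.10, adjusted p = 0.0231), the thioredoxin reductase Txnrd1 (1.10, adjusted p = 0.0239), the co-chaperone Dnajc3 (-0.89, adjusted p = 0.0406), the disulfide isomerase P4hb (-0.78, adjusted p = 0.0464) and Cx3cr1 (-1.14, adjusted p = 0.00218). Without the set these were at 1.08, 1.06, -0.89, -0.74 and -1.21 (adjusted p = 0.0645, 0.0861, 0.0824, 0.216 and 0.0825). The count was 26 without KO replicate 1, 23 without 5xFAD_KO replicate 2, 7 without 5xFAD_KO replicate 1 and 3 without 5xFAD_WT replicate 2. Of the named calls only Esr1 and Pla2g7 passed with each library left out, and DESeq2 called 90 genes. None of the fixed genes passed. The log2 fold changes were 0.73 for Sqstm1 (adjusted p = 0.204), -1.13 for Hspa5 (adjusted p = 0.448), -0.15 for Atf4 (adjusted p = 0.769), -0.34 for Ddit3 (adjusted p = 0.678), 0.20 for Gpx4 and 0.52 for Slc7a11 (adjusted p = 0.760 each). They were 0.55 for Fth1 (adjusted p = 0.553), 0.90 for Apoe (adjusted p = 0.630), -0.17 for P2ry12 (adjusted p = 0.779) and -0.15 for Trem2 (adjusted p = 0.827). Without 5xFAD_WT replicate 1 Atf4, P2ry12 and Trem2 were at 0.03, 0.04 and 0.15, without 5xFAD_WT replicate 2 Gpx4 was at -0.04, and without 5xFAD_KO replicate 3 Slc7a11 was at -0.15 and Trem2 at 0.000443.

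The same lists led in 5xFAD_KO against 5xFAD_WT. NRF2 targets rose (median 0.59, camera adjusted p = 1.88e-27; adjusted p = 0.00976 with an estimated correlation), with 4 members called over all genes and 13 higher adjusted over the list alone. The UPR list was lower (median -0.50, camera adjusted p = 2.66e-17; adjusted p = 0.155 with an estimated correlation), with no member called over all genes, 16 lower adjusted over the list alone and Canx at -0.52 (adjusted p = 0.284). With the set its median was -0.51 and 3 members were called, Dnajc3 and P4hb among them. Ferroptosis defence (median 0.19, 0.000184; adjusted p = 0.0994 with an estimated correlation), iron handling (0.000136; adjusted p = 0.0994 with an estimated correlation) and senescence (5.64e-08; adjusted p = 0.0931 with an estimated correlation) were higher by camera. Homeostatic genes were lower (median -0.26, camera adjusted p = 7.33e-07; adjusted p = 0.0931 with an estimated correlation), a list that includes Cx3cr1. Autophagy receptors (0.0297), inflammatory (0.0190), oxidative phosphorylation (0.000184) and cell cycle (2.06e-15) genes were higher and cholesterol (0.00113) and dissociation (0.0168) genes lower, at adjusted p = 0.370, 0.326, 0.747, 0.184, 0.326 and 0.648 with an estimated correlation. Oxidative phosphorylation had a median of -0.08 without 5xFAD_WT replicate 2. Ferroptosis drivers (0.315), autophagy machinery (0.447), lysosome (0.448), DAM (0.294), interferon (0.934), TGF-beta (0.0619) and the integrated stress response (0.545) did not pass. Marker lists of neutrophils (median -1.34, 5.62e-08), erythroid cells (1.59e-08), monocytes and dendritic cells (0.0216 each) were lower and that of border-associated macrophages higher (4.67e-06). At a correlation estimated from the libraries these were at adjusted p = 0.243, 0.193, 0.603, 0.242 and 0.193.

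The mean Cre effect asked for the average change over both backgrounds, which one of them alone can carry. It was added after the pairwise results had been seen. Gclm (0.97, adjusted p = 0.00449), Txnrd1 (0.79, adjusted p = 0.0234), Srxn1 (1.68, adjusted p = 0.000505) and Blvrb (1.46, adjusted p = 0.000505) rose. The UPR factor Xbp1 (ENSMUSG00000020484) fell by 0.91 ± 0.17 on the log2 scale (adjusted p = 0.0290), from 298 ± 53.8 to 149 ± 41.1 CPM (SD) between WT and KO and from 260.3 ± 44.8 to 148 ± 35.3 CPM between the 5xFAD groups. Dnajc3 (-0.73 ± 0.11, adjusted p = 0.0131), P4hb (-0.66, adjusted p = 0.0290), Pdia4 (-0.83, adjusted p = 0.0413) and Canx (-0.50, adjusted p = 0.0290) fell too, while the chaperone Hspa5 (ENSMUSG00000026864), at -1.10 ± 0.27, did not pass (adjusted p = 0.0923; -0.96 and 0.0481 with the set). The autophagy receptor and NRF2 target Sqstm1 rose by 0.57 ± 0.11 (adjusted p = 0.0410), the lysosomal lipase Lipa by 0.59 (adjusted p = 0.0106), the p53 targets Cdkn1a and Phlda3 by 1.49 and 1.73 (adjusted p = 0.00332 and 0.0280) and the inhibitory receptor Lilrb4a, which has a close paralog, by 1.59 (adjusted p = 0.0385). Cx3cr1 (ENSMUSG00000052336), the locus that carries the driver, fell by 0.98 ± 0.16 (adjusted p = 0.0142). Ferritin heavy chain Fth1 was at 0.48 (adjusted p = 0.212; 0.60 and 0.0111 with the set) and Gpx4 at 0.11 (adjusted p = 0.781).

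For the mean Cre effect 117 genes passed, 67 higher and 50 lower, with 1436 at an unadjusted p under 0.05. With the set as a covariate 736 passed, 326 higher and 410 lower, and these included all 117. The count was 58 and 44 without WT replicates 1 and 2, 43 and 40 without KO replicates 2 and 3, 74 and 67 without 5xFAD_WT replicates 1 and 2, and 42 without 5xFAD_KO replicate 1. Of 29 named calls 12 passed with each library left out, and all 29 passed with the set and all libraries kept. Among those above, Xbp1, P4hb, Txnrd1 and Phlda3 lost their calls in 6 of the 11 fits, Sqstm1 in 8, Pdia4 in 9, Lilrb4a in 10, Cx3cr1 in 3 and Dnajc3 in 1. The UPR list was lower (median -0.49, camera adjusted p = 1.23e-29; adjusted p = 0.0719 with an estimated correlation, fry 0.0156), with 5 members called over all genes and 25 lower adjusted over the list alone. NRF2 targets were higher (median 0.51, camera adjusted p = 5.24e-34; adjusted p = 0.00457 with an estimated correlation), with 9 members called over all genes and 13 higher adjusted over the list alone. Homeostatic genes were lower (median -0.28, camera adjusted p = 5.00e-14; adjusted p = 0.0205 with an estimated correlation), a list that includes Cx3cr1. The camera count was 11 of 25 lists, 17 without WT replicate 1, 19 without 5xFAD_WT replicate 1, 17 without 5xFAD_KO replicate 3 and 18 with the set. Ferroptosis defence passed (0.00142; adjusted p = 0.144 with an estimated correlation, 0.0324 with the set as well). It shares Gclm and Txnrd1, both called for this effect, with the NRF2 list, so it is not a separate result. Marker lists of border-associated macrophages (0.00075), neurons (0.0032), NK cells (0.00902) and T cells (0.0148) were higher by camera, at adjusted p = 0.363, 0.144, 0.618 and 0.634 with an estimated correlation. Those of neutrophils (0.000933), erythroid cells (0.0275) and dendritic cells (0.037) were lower, at adjusted p = 0.618, 0.618 and 0.363 with an estimated correlation. Of the 14 genes higher in KO against WT and the 14 higher in 5xFAD_KO against 5xFAD_WT, 8 were shared (0.0167 expected by overlap alone): Esr1, Pla2g7, Gstm1, Blvrb, B430306N03Rik, Osgin1, Il18bp and A530064D06Rik. All 20 genes called in KO against WT had the same sign in the other background. The log2 fold changes of all genes, without the set, had a Pearson correlation of 0.0316 across genes. Set 2 held all KO libraries and 1 of WT, but 1 of 3 5xFAD_KO and 1 of 2 5xFAD_WT libraries. The set thus entered these contrasts with opposite signs, and no correlation with the set is given.

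**Figure D2:**
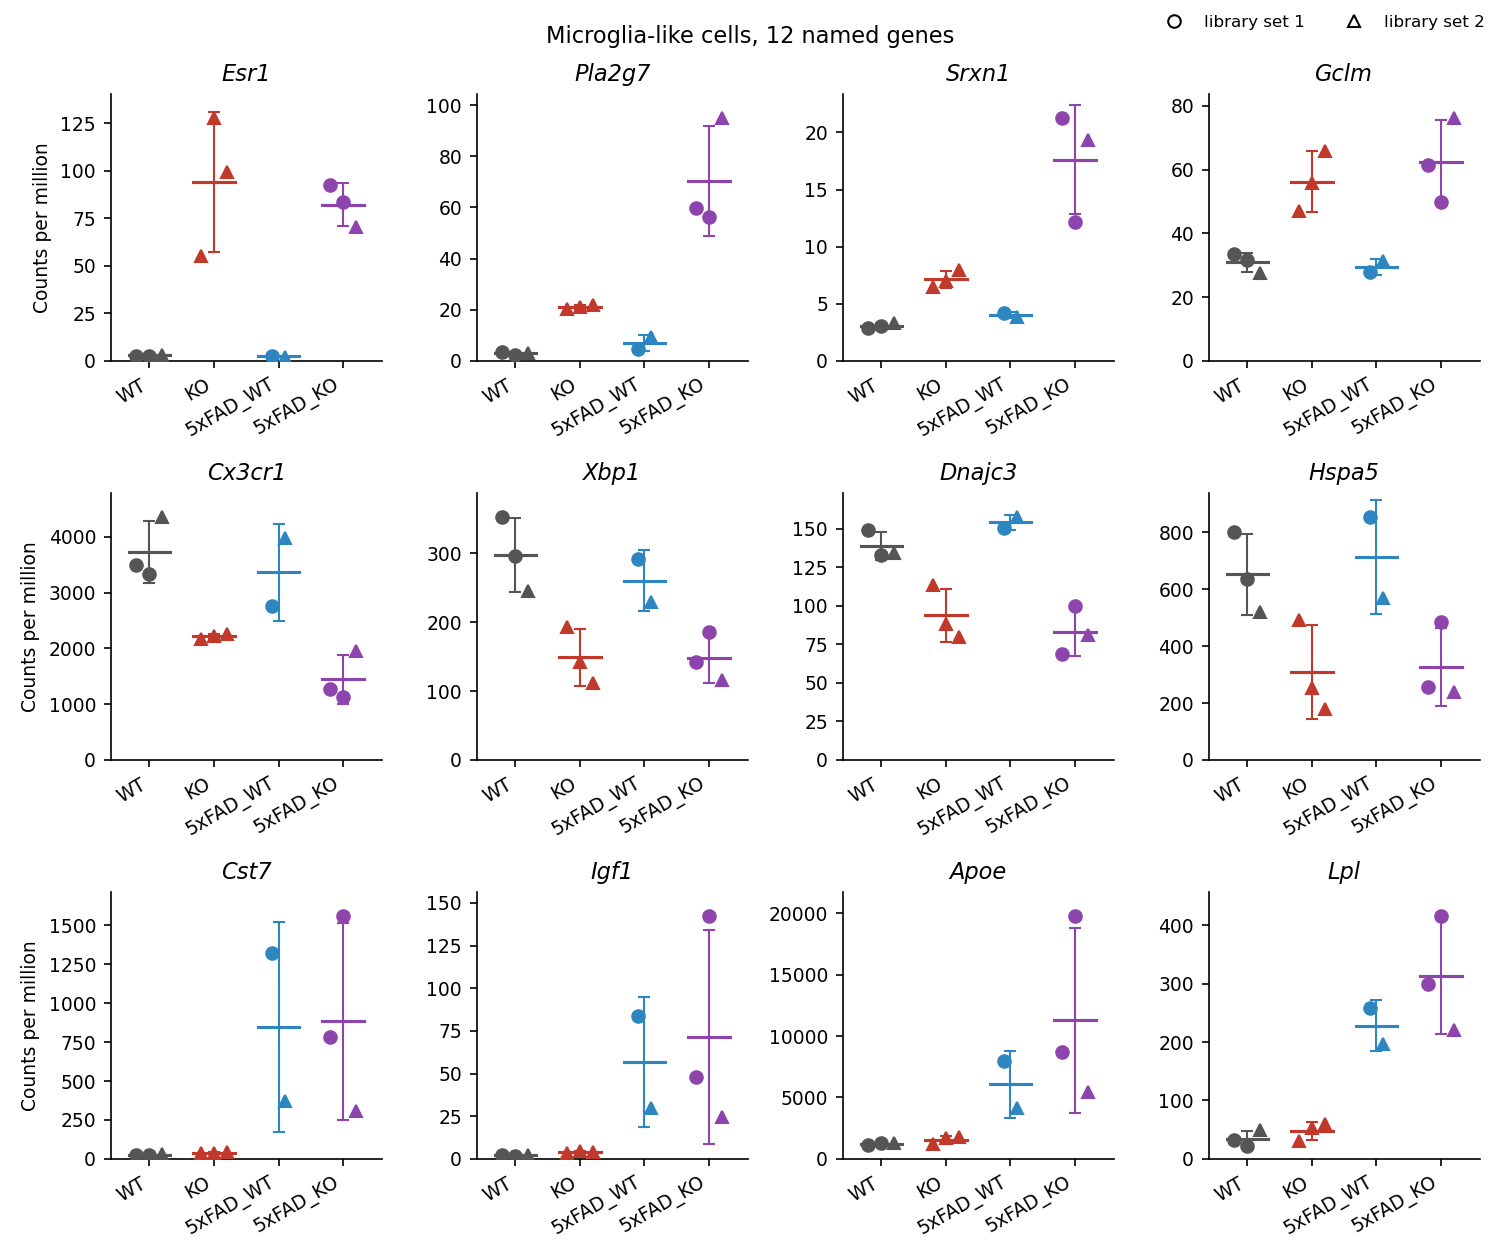
Each panel plots the level of 1 gene in microglia-like cells, in CPM, with 1 point per library (circles set 1, triangles set 2), a line at the group mean and a bar of 1 SD. Esr1 and Pla2g7 are higher in both Cre groups (94.1 and 82.2 CPM for Esr1, against 2.89 and 2.32 without Cre), Xbp1 and Dnajc3 are lower in both, and Cst7 and Lpl are higher in both 5xFAD groups.

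Without Cre, 5xFAD_WT against WT asked how microglia respond to amyloid when Atg7 is intact. Genes of disease-associated microglia were among those that rose and passed. Cst7 (ENSMUSG00000068129), an inhibitor of lysosomal cathepsins, went from 26.5 ± 2.44 CPM (SD, n = 3) to 848 ± 672 (SD, n = 2), a log2 fold change of 5.01 ± 0.62 (adjusted p = 0.0111), and the lipoprotein lipase Lpl from 34.3 ± 14.3 to 228 ± 43.4 CPM (2.75 ± 0.36, adjusted p = 0.0111). The growth factor Igf1 (4.82 ± 0.69, adjusted p = 0.0161), the cholesterol hydroxylase Ch25h (4.24 ± 0.66, adjusted p = 0.0215), the fatty acid binder Fabp5 (3.35 ± 0.50, adjusted p = 0.0188) and the chemokine Ccl3 (2.99 ± 0.43, adjusted p = 0.0161) rose beside the receptors Clec7a (2.65 ± 0.39, adjusted p = 0.0173), Axl (2.64 ± 0.45, adjusted p = 0.0401) and Lilrb4a (3.55 ± 0.47, adjusted p = 0.0111). The interferon-induced Ifi204 (1.38 ± 0.22, adjusted p = 0.0269), a member of a gene family with close paralogs, and Ifit1 (1.28 ± 0.23, adjusted p = 0.0436) rose as well. The genes that fell were the thioredoxin inhibitor Txnip (-0.62 ± 0.11, adjusted p = 0.0401) and the aminoacylase Acy1 (-0.78, adjusted p = 0.0436), which lay under the CPM limit of the naming rule and was named after the values had been seen.

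The 5xFAD_WT against WT count was 37 genes, 35 higher and 2 lower, with 1392 at an unadjusted p under 0.05. With the set as a covariate 625 passed, 513 higher and 112 lower, including all 37, and Oasl2 (1.69, adjusted p = 0.0591) then passed at 0.0144. The count was 0 without WT replicate 1, without WT replicate 2 or without 5xFAD_WT replicate 1 (edgeR), 17 without WT replicate 3, 22 without KO replicate 2, 78 and 102 without 5xFAD_KO replicates 2 and 3, and 308 without 5xFAD_WT replicate 2. No named call passed with each library left out. All 12 named calls passed with the set as a covariate and all libraries kept. DESeq2 called 314 genes. None of the fixed genes passed, and 3 of them did with the set: Fth1 at 0.91 (adjusted p = 0.123; 0.00804 with the set), Apoe at 2.31 (adjusted p = 0.0551; 0.0090 with the set) and Trem2 at 0.53 (adjusted p = 0.283; 0.0448 with the set). Atg7 was at 0.02 (adjusted p = 0.989), Sqstm1 at 0.04 (adjusted p = 0.972), Hspa5 at 0.13 (adjusted p = 0.959), Atf4 at -0.12 (adjusted p = 0.837) and Ddit3 at 0.14 (adjusted p = 0.877). Gpx4 was at 0.27 (adjusted p = 0.598), Slc7a11 at -0.10 (adjusted p = 0.973) and P2ry12 at -0.39 (adjusted p = 0.395). Without 5xFAD_WT replicate 1 Sqstm1, Hspa5 and Gpx4 changed sign to -0.23, -0.19 and -0.01, and without 5xFAD_WT replicate 2 Atf4 went to 0.03 and Atg7 to -0.37. Without WT replicate 1 Slc7a11 was at 0.02 and Atg7 at -0.04, without WT replicate 2 Atg7 was at -0.02, and without WT replicate 3 Hspa5 was at -0.01.

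In 5xFAD_WT against WT the DAM list rose (40 genes, median 1.91, camera adjusted p = 4.95e-65; adjusted p = 0.0450 with an estimated correlation), with 9 members called over all genes and 36 higher adjusted over the list alone. Interferon genes (40 genes, median 1.14, camera adjusted p = 9.40e-37), inflammatory genes (9.19e-08) and lipid handling genes (7.67e-08) rose too, each at adjusted p = 0.0450 with an estimated correlation. Lysosomal genes were higher (median 0.27, camera adjusted p = 3.04e-07; adjusted p = 0.330 with an estimated correlation) and homeostatic genes lower (median -0.21, 3.11e-06; adjusted p = 0.0885 with an estimated correlation). NRF2 targets (0.00175), MHC class I (5.60e-09), MHC class II (9.27e-05), phagocytic receptors (0.00243), cholesterol (0.00031), glycolysis (2.69e-06), oxidative phosphorylation (1.68e-09), cell cycle (7.81e-05) and senescence (0.0189) were higher by camera, at adjusted p between 0.232 and 0.441 with an estimated correlation. The UPR (median 0.12, 0.386), ferroptosis defence (0.223), ferroptosis driver (0.520) and integrated stress response (0.382) lists did not pass. The number of lists was 15, and 7 without 5xFAD_WT replicate 1. Marker lists of neutrophils (median 1.28, 1.24e-06; adjusted p = 0.388 with an estimated correlation), erythroid cells (median 6.17, 1.24e-06; adjusted p = 0.306 with an estimated correlation), astrocytes (2.95e-06; adjusted p = 0.0573 with an estimated correlation) and monocytes (0.000127; adjusted p = 0.456 with an estimated correlation) were higher as well. The erythroid value leaves out unnamed cluster c33, which held hemoglobin together with microglia genes. Of its cells 52.5% were from WT and 1.45% from 5xFAD_WT libraries. Whether leaving it out gave the erythroid difference was not tested.

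In the Cre genotype, 5xFAD_KO against KO asked whether microglia still mount the amyloid response. Cst7 rose by a log2 fold change of 4.47 ± 0.58 (adjusted p = 0.0139), from 40.0 ± 6.30 to 884 ± 634 CPM (SD, n = 3 each), and the lipid carrier Apoe by 2.87 ± 0.42 (adjusted p = 0.0149), from 1548 ± 306 to 11295 ± 7532 CPM. Ch25h (4.32 ± 0.59, adjusted p = 0.0149), Igf1 (4.16 ± 0.63, adjusted p = 0.0164), Ccl3 (2.77 ± 0.41, adjusted p = 0.0149), Fabp5 (2.74 ± 0.46, adjusted p = 0.0274), Lpl (2.72 ± 0.34, adjusted p = 0.0127) and Wfdc17 (2.72 ± 0.45, adjusted p = 0.0261) rose beside it. The iron store gene Fth1 rose by 1.05 ± 0.21 (adjusted p = 0.0451), though its pseudogenes can share reads, the antioxidant genes Srxn1 by 1.30 ± 0.20 (adjusted p = 0.0164) and Txn1 by 0.53 (adjusted p = 0.0359), and the chemokine Cxcl16 by 1.06 (adjusted p = 0.0205). Genes that fell included the semaphorin Sema4b (-0.98 ± 0.19, adjusted p = 0.0388), the kinase Prkca (-0.89 ± 0.13, adjusted p = 0.0161), Col27a1 (-0.87 ± 0.14, adjusted p = 0.0237), the GTPase Gimap6 (-0.74, adjusted p = 0.0289), Lrba (-0.72, adjusted p = 0.0179), the lipase Mgll (-0.61, adjusted p = 0.0396) and Fam91a1 (-0.54, adjusted p = 0.0396).

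The 5xFAD_KO against KO count was 100, 91 higher and 9 lower, with 2721 genes at an unadjusted p under 0.05. With the set as a covariate, where the contrast leans on 5xFAD_KO replicate 3, 29 passed, 23 higher and 6 lower, and 27 were shared. Cst7 (3.48, adjusted p = 0.0253), Ch25h (3.03, adjusted p = 0.0124), Lpl (2.68, adjusted p = 0.0265) and Srxn1 (adjusted p = 0.0447) kept their calls. Of the 26 named calls 10 were kept and 16 lost. Igf1 (2.89 ± 0.51), Apoe (2.31 ± 0.40) and Ccl3 (2.23 ± 0.39) were at adjusted p = 0.0508 each, and Fabp5 (1.92 ± 0.44) at 0.123, Fth1 (0.72 ± 0.15) at 0.106 and Wfdc17 (2.17 ± 0.54) at 0.150. Sema4b (-0.83 ± 0.19), Mgll (-0.50 ± 0.11) and Fam91a1 (-0.45 ± 0.09) were at adjusted p = 0.122, 0.106 and 0.105, and Ifi204 (1.10 ± 0.23) and Ifi44 (2.52 ± 0.59) at 0.106 and 0.132. The count was 0 without KO replicate 1, KO replicate 3 or 5xFAD_KO replicate 1 (edgeR), 1 without KO replicate 2 and 24 without 5xFAD_KO replicate 2. It was 36, 49 and 53 without WT replicates 1, 2 and 3, 703 and 698 without 5xFAD_WT replicates 1 and 2, and 1366 without 5xFAD_KO replicate 3. None of the 26 named calls passed with each library left out, and DESeq2 called 763 genes. Atg7 was at -0.43 (adjusted p = 0.25), Sqstm1 at 0.35, Hspa5 at 0.08, Atf4 at 0.16, Ddit3 at 0.02, Gpx4 at 0.46, Slc7a11 at 0.09, P2ry12 at -0.13 and Trem2 at 0.47, none of which passed. Hspa5 was at -0.05 and -0.19 without KO replicates 2 and 3 and -0.31 without 5xFAD_KO replicate 2, and at -0.32 with the set. Ddit3 was at -0.02 and -0.04 without KO replicates 2 and 3, -0.02 and -0.07 without 5xFAD_KO replicates 1 and 2, and -0.28 with the set. Slc7a11 was at -0.57 without 5xFAD_KO replicate 3, and Atf4 at -0.02 with the set.

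Camera passed 17 lists in 5xFAD_KO against KO, none of them with an estimated correlation. DAM genes were higher (median 1.59, camera adjusted p = 1.10e-41; adjusted p = 0.139 with an estimated correlation), with 15 members called over all genes and 39 higher adjusted over the list alone. Interferon genes, including Ifi204 (1.20, adjusted p = 0.0277) and Ifi44 (2.91, adjusted p = 0.0359), had a median of 0.80 (3.81e-17; adjusted p = 0.139 with an estimated correlation). NRF2 targets (median 0.35, 3.84e-07; adjusted p = 0.139 with an estimated correlation) and lysosomal genes (median 0.48, 4.83e-10; adjusted p = 0.224 with an estimated correlation) were higher. Ferroptosis defence (0.00214; adjusted p = 0.163 with an estimated correlation) and iron handling (0.0252; adjusted p = 0.224 with an estimated correlation) were higher by camera, with 1 ferroptosis defence member called over all genes and 8 adjusted over the list alone. The other lists that passed were the integrated stress response (0.00102), MHC class I (0.000769), inflammatory (3.23e-05), phagocytic receptor (0.00179), lipid handling (0.000224), glycolysis (4.81e-06), oxidative phosphorylation (2.36e-13), proteasome (0.0139), cell cycle (1.62e-08) and senescence (0.000162) lists, all higher, and homeostatic genes, lower (0.00334), at adjusted p between 0.139 and 0.591 with an estimated correlation. MHC class I and proteasome did not pass with the set (0.0839 and 0.681), and the DAM median was then 1.04. The UPR (0.288) and ferroptosis driver (0.0702) lists did not pass.

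The mean 5xFAD effect, also added after the pairwise results, asked for the average amyloid response over both Cre genotypes. Spp1, an osteopontin gene of plaque-associated microglia, rose by 5.14 ± 0.83 (adjusted p = 0.00575), Cst7 by 4.74 ± 0.43 (adjusted p = 0.000382), Igf1 by 4.49 ± 0.47 (adjusted p = 0.000662), Apoe by 2.59 ± 0.30 (adjusted p = 0.00119) and Lpl by 2.73 ± 0.25 (adjusted p = 0.000384). The iron and heme genes Fth1 (0.98 ± 0.15, adjusted p = 0.00561), Ftl1 (0.87 ± 0.16, adjusted p = 0.00867) and Hmox1 (0.60 ± 0.14, adjusted p = 0.0224) rose with the lipid-sensing receptor Trem2 (0.50 ± 0.13, adjusted p = 0.0397). Ftl1, like Fth1, has pseudogenes that can share its reads. The purinergic receptor P2ry13 fell by 0.37 ± 0.08 (adjusted p = 0.0224), and Atg7 was at -0.20 ± 0.16 (adjusted p = 0.475). In total 808 genes passed, 624 higher and 184 lower, with 2609 at an unadjusted p under 0.05, and 1313 with the set, 833 higher and 480 lower, of which 797 were shared. The count was 419, 535 and 534 without WT replicates 1, 2 and 3, 350 and 432 without KO replicates 2 and 3, and 273 and 1547 without 5xFAD_WT replicates 1 and 2. It was 492, 464 and 1346 without 5xFAD_KO replicates 1, 2 and 3. Of 62 named calls 34 passed with each library left out, and 61 passed with the set and all libraries kept. Trem2 lost its call in 9 of the 11 fits, P2ry13 in 5 and Hmox1 in 4. DAM (median 1.77, camera adjusted p = 2.50e-69), interferon (1.54e-33), inflammatory (4.38e-08) and lipid handling (1.38e-07) genes were higher, each at adjusted p = 0.0432 with an estimated correlation, and 37, 27, 13 and 7 of their members were called over all genes. Marker lists of astrocytes (0.00294; adjusted p = 0.252 with an estimated correlation) and neutrophils (0.0343; adjusted p = 0.974 with an estimated correlation) were higher by camera. Of the 35 genes higher in 5xFAD_WT against WT, 23 were among the 91 higher in 5xFAD_KO against KO (0.272 expected by overlap alone), and 35 of all 37 called genes had the same sign there. Across all genes the Pearson correlation of the log2 fold changes was 0.373 without the set, which was not balanced in these contrasts either.

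**Figure D3:**
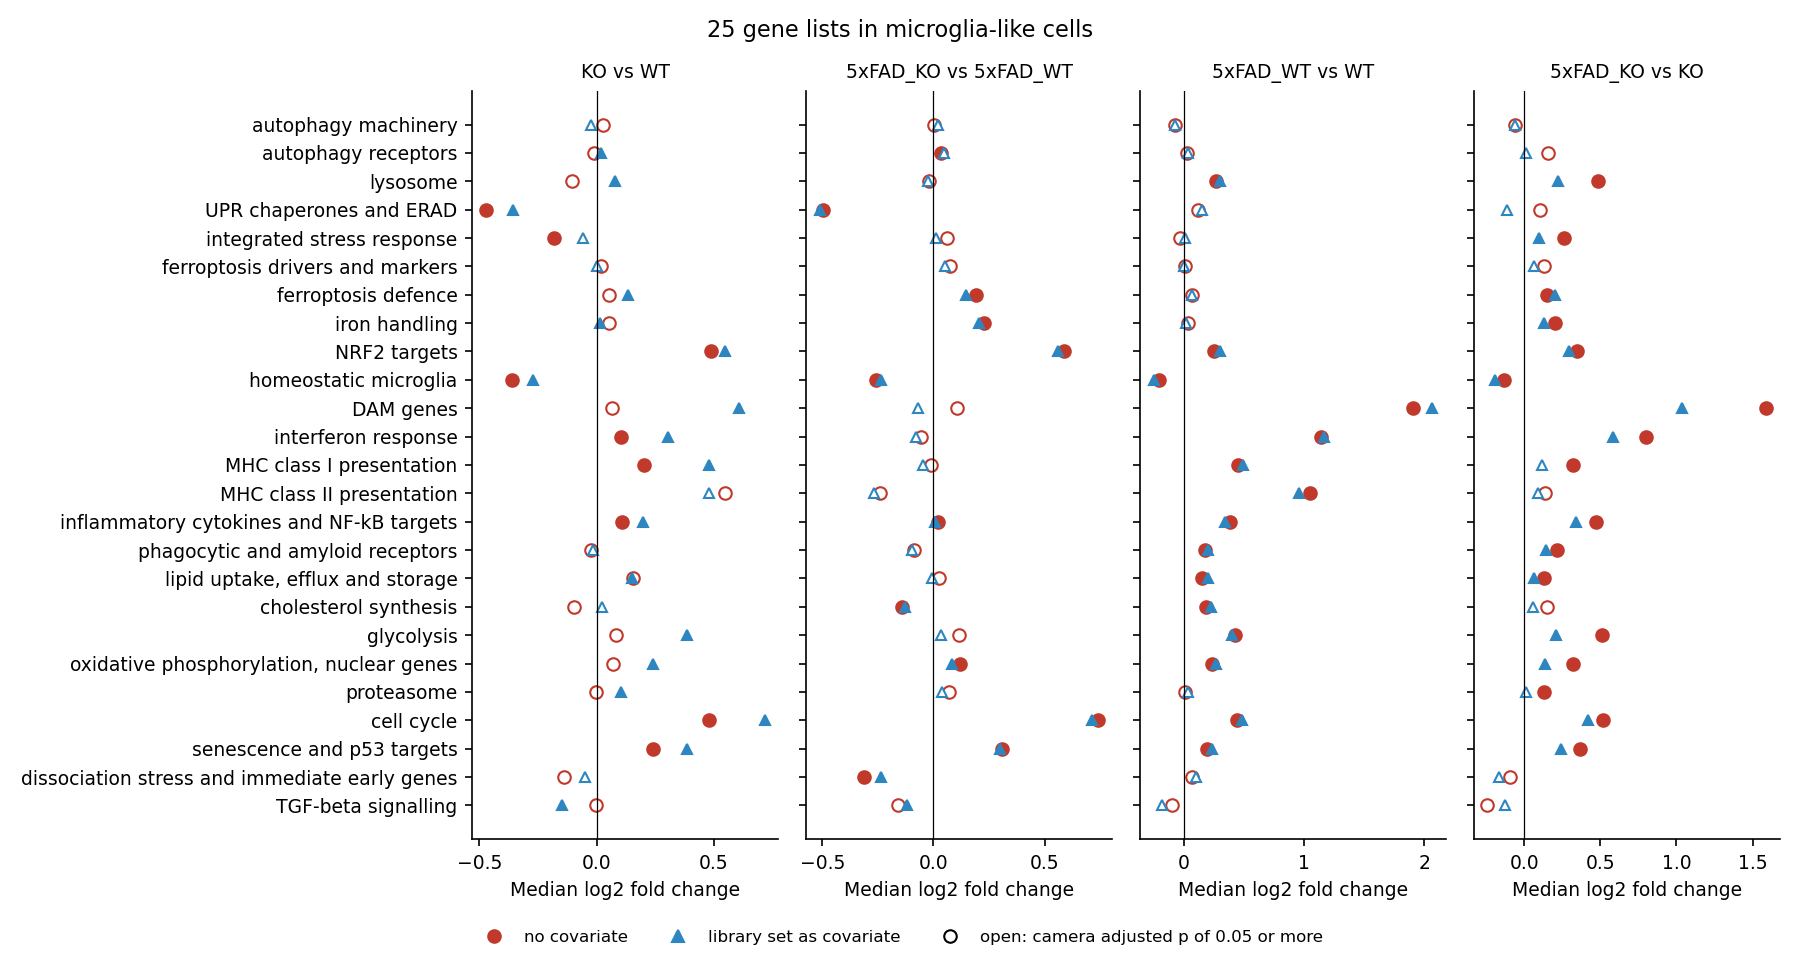
Each panel is 1 pairwise comparison and plots the median log2 fold change of 25 gene lists in microglia-like cells, red circles without a covariate and blue triangles with the library set, open where the camera adjusted p was 0.05 or more. NRF2 targets lie at 0.49 and 0.59 and the UPR list at -0.47 and -0.50 in the 2 Cre comparisons, and DAM genes at 1.91 and 1.59 in the 2 5xFAD comparisons.

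The interaction asked whether the Cre genotype acted differently in plaque-bearing cortex. No gene passed in edgeR, with 645 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.732, and DESeq2 called 0 as well. With the set as a covariate the edgeR count was 0, with 571 genes at an unadjusted p under 0.05. With a replicate block it was 5 genes, all lower, though replicate numbers did not pair the libraries: the hemoglobin genes Hba-a2, Hba-a1, Hbb-bs and Hbb-bt (log2 differences of -17.34, -17.09, -16.54 and -17.28, edgeR adjusted p at most 0.00109) and 3830403N18Rik (-1.69, adjusted p = 0.00994), which were chosen after the values had been seen. Camera then passed 3 lists. Atg7 and the 10 genes fixed in advance were among those that did not pass. None of the 25 lists passed camera (smallest adjusted p = 0.0811), and none did with an estimated correlation or with fry. With the set 10 lists passed camera, led by lower DAM genes (median -0.69, 1.72e-12), MHC class I (1.65e-07), interferon (4.56e-06) and oxidative phosphorylation (4.85e-06), and the UPR list was at 0.0110 (median -0.22). None of these 10 passed with an estimated correlation (smallest adjusted p = 0.414). The list count was 4 and 3 without WT replicates 1 and 3, 2, 1 and 2 without KO replicates 1, 2 and 3, 8 without either 5xFAD_WT library, and 5, 6 and 4 without 5xFAD_KO replicates 1, 2 and 3.

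The share of cells asked whether the genotype changed how many microglia were recovered or how many had entered the disease-associated state. The CD45 gate fixes what can be counted, so these shares are of sorted cells and not of tissue. Microglia-like cells made up 65.2 ± 4.71% of named and unnamed cells in WT, 59.0 ± 4.70% in KO, 53.3 ± 11.6% in 5xFAD_WT and 58.0 ± 3.01% in 5xFAD_KO (SD, n = 3, 3, 2 and 3). The Cre difference was -0.76 percentage points (exact permutation p = 0.845; -0.03 within library sets, exact permutation p = 1), at 0.50, 0.59 and 3.35 without WT replicate 3, KO replicate 1 and 5xFAD_WT replicate 1. The 5xFAD difference was -6.45 points (exact permutation p = 0.140; -8.03 within sets, exact permutation p = 0.667), at -10.6 and -2.35 without 5xFAD_WT replicates 1 and 2. DAM-high cells were 5.20 ± 1.15% of microglia-like cells in WT, 7.22 ± 1.18% in KO, 28.7 ± 15.3% in 5xFAD_WT and 43.6 ± 19.5% in 5xFAD_KO. They were more frequent with 5xFAD by 29.98 points (exact permutation p = 0.005, the smallest possible), and by 22.001 points within sets (exact permutation p = 0.0417, the smallest possible). The Cre difference was 8.46 points (exact permutation p = 0.310), 2.03 without and 14.9 with 5xFAD, and 8.02 within sets (exact permutation p = 0.208). Without 5xFAD_KO replicate 3, at 25.5% the lowest of its group, the Cre difference was 13.005 points (exact permutation p = 0.033). It was 13.87 without 5xFAD_WT replicate 1, 3.05 without 5xFAD_WT replicate 2 and 3.33 without 5xFAD_KO replicate 2 (exact permutation p = 0.275, 0.525 and 0.367). Among 18 tests of other cell classes none passed after adjustment. The smallest unadjusted p for Cre was in T cell-like cells (3.42 points, exact permutation p = 0.020, adjusted p = 0.180; 3.19 within sets, exact permutation p = 0.125), and the largest difference in neutrophil-like cells (-3.48 points, exact permutation p = 0.210, adjusted p = 0.450; -3.73 within sets, exact permutation p = 0.875). The largest 5xFAD difference was in neutrophil-like cells (5.38 points, exact permutation p = 0.020, adjusted p = 0.180; 6.22 within sets, exact permutation p = 0.25).

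**Figure D4:**
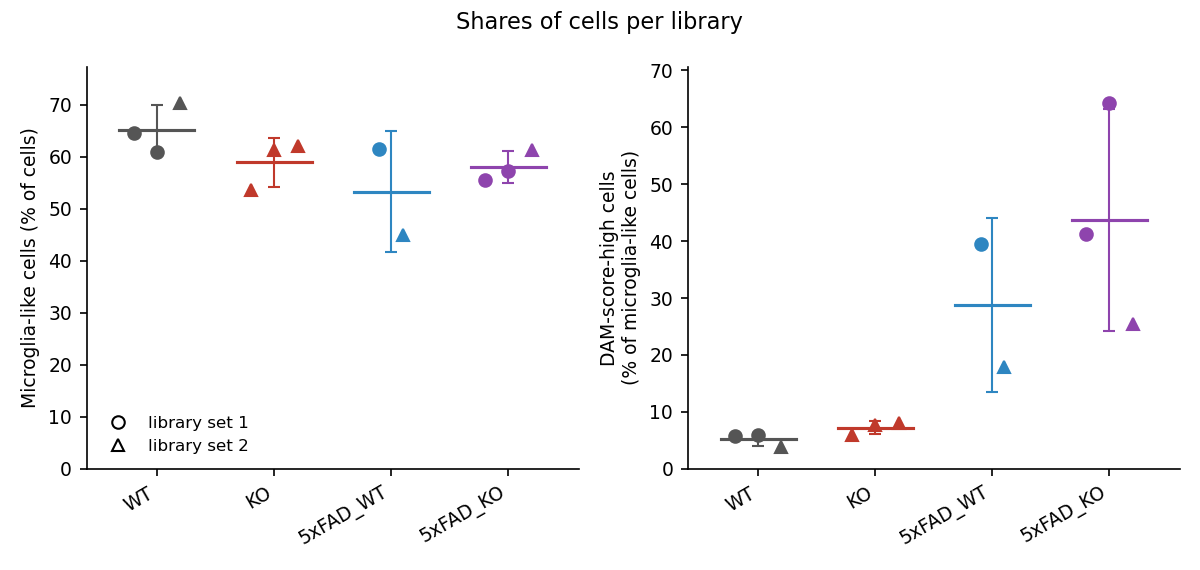
Points are libraries, lines group means and bars 1 SD; the left panel plots microglia-like cells as a percentage of all kept cells and the right panel DAM-high cells as a percentage of microglia-like cells, per genotype group. DAM-high cells lie between 3.87 and 8.12% in the libraries without 5xFAD and between 17.9 and 64.2% in those with it.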

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

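The tests of insert reads and of free RNA for Esr1, of the library set for the UPR genes, the comparison of the Esr1 to Cx3cr1 ratio, and both tests of the library sets were chosen only after the results were seen, as were the library set and neutrophil covariates.

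Marker genes of other cell types differed between the Cre contrast with 5xFAD and the Cre contrast without it, by a camera test of the interaction over 13 marker lists in the microglia-like sums. Border-associated macrophage markers were higher in the first (adjusted p = 0.0053; adjusted p = 0.326 with an estimated correlation). Markers of monocytes (8.04e-06), neutrophils (9.43e-06), T cells (0.00741), astrocytes (0.0114) and erythroid cells (4.19e-13) were lower, at adjusted p = 0.326, 0.326, 0.444, 0.326 and 0.160 with an estimated correlation. No marker list passed with the estimated correlation, and no explanation of these differences was tested.

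Esr1 was raised in cells that the comparisons above do not use. In sums of monocyte-like cells the mean Cre effect on Esr1 was a log2 fold change of 2.97 (adjusted p = 0.0259), and in border-associated macrophage-like cells it was 2.39 (adjusted p = 5.69e-05). With the library set as a covariate the Esr1 values were 3.16 (adjusted p = 0.0382) and 2.41 (adjusted p = 4.67e-05). Esr1 in the Cre libraries was at 34.0 CPM in border-associated macrophage-like cells (20.5 to 44.9 over the libraries), 2.52 times the highest of the named classes other than microglia and monocytes (13.5 in choroid plexus-like cells). The unnamed cells, left out of that comparison, were at 18.8 CPM. In 5xFAD_KO replicate 3 they were at 20.8, against 20.5 in border-associated macrophage-like cells. The unnamed cells were mixed, so their level is not a measure of free RNA alone. Cluster c17, whose highest marker score was for border-associated macrophages, was at 37.6 CPM in the Cre libraries. Clusters c7 and c12, with high doublet scores, were at 28.3 and 30.2, and cluster c30 at 2.58. By the named classes alone, free microglial RNA is argued against as the whole cause in border-associated macrophage-like cells, while microglia caught in the same droplets were not tested. At 11.4 CPM it was not excluded in monocyte-like cells.

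Esr1 in the Cre libraries was weighed first. A candidate explanation is that 3′ reads of the CreERT2 insert, which contains an estrogen receptor ligand-binding domain, were counted as Esr1. Whether reads of the insert can align to mouse Esr1 was not tested. Over 34 clusters of the Cre libraries the Esr1 and Cx3cr1 levels had a Spearman rho of 0.895, against 0.381 over 35 clusters of the libraries without Cre, and 0.817 over the 9 microglia-like clusters, where clusters are not independent samples. Free microglial RNA would also tie Esr1 to Cx3cr1 across cell types, as the ratio of their UMIs in the Cre libraries was 0.046 in microglia-like, 0.0395 in monocyte-like, 0.0436 in T cell-like, 0.0448 in dendritic-like and 0.047 in NK cell-like cells. It was 0.0298 in neutrophil-like, 0.0568 in choroid plexus-like, 0.0635 in border-associated macrophage-like, 0.159 in B cell-like and 0.2 in mast cell-like cells, the last from 2 Esr1 UMIs. The value within microglia-like clusters leaves out other cell types, but free RNA within those droplets was not tested. Whether Esr1 was induced together with the NRF2 genes cannot be told. The NRF2 targets called in microglia-like cells had a median log2 fold change of 0.0642 in monocyte-like cells (interquartile range 0.206) where Esr1 rose, against 0.970 in microglia-like cells. The prediction written beforehand counted this against it, but that Esr1 could be free RNA of microglia, and in border-associated macrophage-like cells, where Esr1 rose as well, the median was 0.788 (interquartile range 0.785). If the insert is the source, Esr1 marks cells carrying the driver and says nothing of estrogen signalling.

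The lower UPR genes in the Cre libraries were weighed next. A shift in which microglia clusters were present is argued against as the whole cause, because the list's median averaged -0.49 over the 9 microglia-like clusters tested singly (range -0.74 to -0.25, lower in 9 of 9), as in the summed cells. Free RNA of neutrophils and the library sets are argued against as the whole cause as well, with medians of -0.44 with the neutrophil covariate and -0.41 with the library set, though with the set the adjusted p was 0.134 at an estimated correlation against 0.0719 without it. An effect of the driver insertion and the loss of Atg7 cannot be told apart, as the design has 0 groups with Cre and without floxed Atg7. A biological reading, in which loss of Atg7 may lower endoplasmic reticulum folding capacity, stays open and rests on the same libraries in which the pattern was found.

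The library sets were weighed last. Handling or preparation of the libraries may have produced them, since the set effects in microglia-like and T cell-like cells had a Pearson correlation of 0.81 across genes. T cell-like cells had defined the sets, and the correlations were 0.549, 0.675 and 0.698 with B cell-like, neutrophil-like and monocyte-like cells, where 226, 11 and 87 genes differed. The labels name no date or run that would show which step. A genotype effect is argued against as the whole cause of the sets, because 3 of the groups had libraries in both sets. All 3 KO libraries were in set 2, so a part of it is not excluded. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d had at most 3 UMIs in the microglia-like sum of any library, which gives no sign of a difference in sex. A difference in litter would also act in several cell types and was not tested.

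Other splits of the libraries were counted for each comparison with at least 3 libraries per side. For KO against WT the real split gave 20 genes and the highest of the others 0, and for 5xFAD_KO against KO 100 and 1, but in each case 1 of 10 splits is too few for a share under 0.05. For the mean Cre effect 3 of 100 splits gave at least 117 genes, the real one included. This share was under 0.05, but chance was not excluded, as the others of these 3 gave far more genes than the real split. The others reached 2070 and 1994 genes, and both put the libraries of set 1 against those of set 2 but for 1 library, which points to the structure of the samples. With the set as a covariate the value was 736, and 1 of 24 splits, the real one, gave as many, with 6 the highest of the others. For the mean 5xFAD effect 1 of 100 splits, the real one, gave at least 808 genes, the highest other being 741, a split that exchanged WT replicate 2 for 5xFAD_WT replicate 2. With the set it was 1 of 24, with 1313 genes against 31. The smallest share that 24 splits can give is 0.0417, and the set was chosen after the data had been seen. Chance is therefore argued against for both mean effects with the set, but not excluded.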

How the results depend on the processing

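Chosen only after results were seen were the library set and neutrophil covariates, the omission of KO replicate 1 with 5xFAD_WT replicate 2, and every alternative of the mean Cre and mean 5xFAD effects. Over all alternatives, 298 count values had 183 within 1.5 times the main count and 115 beyond. Of 8581 single-gene values 135 reversed, 133 of them in genes that had not passed, and among values of called genes 2547 kept direction and call, 833 kept direction alone and 2 reversed, both with all cells summed (Nusap1 at -0.16 and Tk1 at -0.0315 for the mean Cre effect, against 1.19 and 0.92, named after their values had been seen). Of 1545 list values 4 reversed and 157 lost their call. The interaction gave 242 values over 11 genes, of which 32 changed sign and 0 passed in any alternative. Reversed values are listed below for genes of the report alone. For the values below the cause was not tested, except where a smaller sample, fewer libraries or more genes tested is the alternative itself. The alternative with Xist as a covariate was not run, as the gene is absent.

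DESeq2 called 135 genes in KO against WT, 90 in 5xFAD_KO against 5xFAD_WT, 314 in 5xFAD_WT against WT, 763 in 5xFAD_KO against KO and 308 for the mean Cre effect. With no filter on low counts the numbers were 43, 36, 207, 466 and 181. With only the compared groups in the model, KO against WT had 38, 5xFAD_KO against 5xFAD_WT 5 and 5xFAD_KO against KO 362.

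With all cells summed, where other cell types dilute microglia, the counts were 1 for KO against WT, 1 for 5xFAD_KO against 5xFAD_WT, 0 for 5xFAD_WT against WT and 0 for 5xFAD_KO against KO (edgeR), 3 for the mean Cre and 20 for the mean 5xFAD effect. Reversed values were -0.13 for Apoe and -0.0288 for Gpx4 in KO against WT, -0.0714 for Gclm, -0.00887 for Gpx4 and -0.0753 for Slc7a11 in 5xFAD_KO against 5xFAD_WT, and -0.0446 for Ddit3 and -0.0439 for Slc7a11 in 5xFAD_KO against KO. In 5xFAD_WT against WT they were -0.0361 for Hspa5, 0.41 for Slc7a11 and -0.0136 for Sqstm1. Atg7 was 0.0668 for the mean 5xFAD and Gpx4 -0.0188 for the mean Cre effect.

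With the library set as a covariate the counts were 79 for 5xFAD_KO against 5xFAD_WT, 625 for 5xFAD_WT against WT, 29 for 5xFAD_KO against KO, 736 for the mean Cre and 1313 for the mean 5xFAD effect. List counts were 18 for KO against WT, 10 for the interaction and 18 for the mean Cre effect. Reversed values were 0.0798 for Ddit3, -0.17 for Slc7a11 and 0.13 for Trem2 in KO against WT, -0.11 for Atg7 in 5xFAD_WT against WT, and -0.0223 for Atf4, -0.28 for Ddit3 and -0.32 for Hspa5 in 5xFAD_KO against KO.

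With the neutrophil marker level as a covariate the counts were 8 for KO against WT, 7 for 5xFAD_KO against 5xFAD_WT, 0 for 5xFAD_WT against WT (edgeR), 41 for the mean Cre and 371 for the mean 5xFAD effect, and 2 lists for the interaction. Reversed values were -0.0844 for Ddit3, -0.26 for Hspa5 and 0.39 for Slc7a11 in 5xFAD_WT against WT, and -0.0834 and -0.0352 for Slc7a11 in 5xFAD_KO against 5xFAD_WT and against KO.

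With a replicate block, although replicate numbers did not pair the libraries, 23 genes passed in 5xFAD_KO against 5xFAD_WT, 5 for the interaction and 521 for the mean 5xFAD effect, and 3 lists for the interaction and 17 for the mean Cre effect. Reversed values were -0.11 for Hspa5 and 0.10 for Slc7a11 in 5xFAD_WT against WT and -0.0151 for Slc7a11 in 5xFAD_KO against KO.

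Without KO replicate 1 and 5xFAD_WT replicate 2 together, 2 genes passed in 5xFAD_KO against 5xFAD_WT, 279 in 5xFAD_WT against WT, 326 in 5xFAD_KO against KO and 1252 for the mean 5xFAD effect, and 8 lists for the interaction. Reversed values were 0.0259 for Atf4 and -0.37 for Atg7 in 5xFAD_WT against WT and -0.0385 for Gpx4 in 5xFAD_KO against 5xFAD_WT. Lists count as reversed by the direction of camera, not by the sign of the median. By that rule oxidative phosphorylation reversed in 5xFAD_KO against 5xFAD_WT (median -0.0751) and for the mean Cre effect (median 0.000142).

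Thinned to the smallest library, 24 genes passed in 5xFAD_WT against WT and 193 in 5xFAD_KO against KO, and in the former Atg7 was -0.0675, Slc7a11 0.23 and Sqstm1 -0.0134. With the stricter cell filter Hspa5 was -0.00575 in 5xFAD_KO against KO. Doublets kept and RLE size factors moved no count beyond 1.5 times. The lower clustering resolution was run for the microglia-like share alone, with differences of -0.562 points for Cre and -6.46 for 5xFAD.

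At an estimated correlation camera passed 2 lists for KO against WT, 1 for 5xFAD_KO against 5xFAD_WT, 4 for 5xFAD_WT against WT, 0 for 5xFAD_KO against KO, 2 for the mean Cre and 4 for the mean 5xFAD effect. Fry passed 2, 5 and 5 for the first 3 and 6 for the mean Cre effect.

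With each library left out in turn, gene counts ranged from 5 to 26 for KO against WT, 3 to 26 for 5xFAD_KO against 5xFAD_WT, 0 to 308 for 5xFAD_WT against WT, 0 to 1366 for 5xFAD_KO against KO, 40 to 118 for the mean Cre and 273 to 1547 for the mean 5xFAD effect. Without either 5xFAD_WT library the remaining 1 was assumed to vary like the other groups. List counts ranged from 7 to 16 for 5xFAD_WT against WT, 0 to 8 for the interaction and 9 to 19 for the mean Cre effect. In KO against WT Atg7 ranged from -0.12 to 0.0465 and Gpx4 from -0.0631 to 0.0927. In 5xFAD_KO against 5xFAD_WT Atf4 ranged from -0.30 to 0.0278, Gpx4 from -0.0398 to 0.51, P2ry12 from -0.35 to 0.0432, Slc7a11 from -0.15 to 0.86, Trem2 from -0.38 to 0.15 and the oxidative phosphorylation median from -0.0764 to 0.37. For the mean Cre effect that median ranged from -0.000103 to 0.20 and Gpx4 from -0.0116 to 0.27. In 5xFAD_WT against WT Atg7 ranged from -0.37 to 0.34, Atf4 from -0.27 to 0.0268, Gpx4 from -0.0115 to 0.51, Hspa5 from -0.19 to 0.39, Slc7a11 from -0.24 to 0.0230 and Sqstm1 from -0.23 to 0.27. In 5xFAD_KO against KO Ddit3 ranged from -0.0731 to 0.22, Hspa5 from -0.31 to 0.59 and Slc7a11 from -0.57 to 0.44. The Cre difference ranged from -4.86 to 3.35 points in the microglia-like share and from 3.05 to 13.9 in the DAM-high share, which passed without 5xFAD_KO replicate 3 (13.005).

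Slc7a11 lay between 2.23 and 3.19 CPM in the group means, and its sign changed under several alternatives. Depth was not tested as the cause. The median depth of set 2, 2226 to 2746 UMIs per cell, was below that of set 1.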

Other observations

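The relation of S100a8 to the neutrophil share and the tests with the library set were chosen only after the data had been seen.

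Cell classes other than microglia were summed per library and tested for the mean Cre and mean 5xFAD effects. In border-associated macrophage-like cells, which also express Cx3cr1, 50 of 7559 genes passed for the Cre effect (24 higher and 26 lower, 656 at an unadjusted p under 0.05; 34 and 32 with the library set). Genes that rose there included the detoxifying Mgst1 (log2 fold change 1.66), Gstm1 (1.10) and Cat (0.96), the iron exporter Slc40a1 (0.61), Fth1 (0.44), the lipase Lipa (0.57) and Esr1 (2.39). Those that fell included Cx3cr1 (-1.37) and the folding genes Hspa5 (-0.61), Calr (-0.80), Xbp1 (-0.59), Pdia6 (-0.67), Sdf2l1 (-0.66) and Manf (-0.65), with the microglia genes Crybb1 (-1.04), Sall1 (-1.01), Siglech (-0.64) and Fcrls (-0.59), and these genes were chosen after their values had been seen. The UPR list had a median of -0.27 in these cells and -0.27 with the set, and in monocyte-like, T cell-like, B cell-like, neutrophil-like and dendritic-like cells it was 0.0142, -0.0104, -0.000677, -0.18 and -0.11. Monocyte-like cells had 2 changed genes, Esr1 (2.97) and Cx3cr1 (-0.99), and T cell-like cells 1, Cx3cr1 (-0.996). Dendritic-like cells had 14, all lower, among them Cx3cr1 (-1.55) and P2ry12 (-1.05). Neutrophil-like cells had 0 (edgeR, 400 at an unadjusted p under 0.05). For the 5xFAD effect Cst7 passed in border-associated macrophage-like (3.69), neutrophil-like (3.39), B cell-like (3.62), monocyte-like (3.59), dendritic-like (2.33) and choroid plexus-like cells (4.69), and not in T cell-like or NK cell-like cells. Free microglial RNA was tested for Esr1 in border-associated macrophage-like cells alone, so the other values are not read as expression by the classes named.

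S100a8, a neutrophil gene, was at 476 to 4099 CPM in microglia-like cells and 202042 to 227573 CPM in neutrophil-like cells. Over the 11 libraries its level in microglia-like cells and the share of neutrophil-like cells had a Spearman rho of 0.673 (permutation p = 0.0272) and a Pearson correlation of 0.911 (permutation p = 0.00286), with 100000 resamples and 1 relation computed. Without 5xFAD_WT replicate 2 and WT replicate 3, the libraries farthest from the median share, the correlation was 0.448, so the relation rests on those samples. The S100a8 level of T cell-like cells over that of microglia-like cells had a median of 0.791 (0.720 to 0.895 over the libraries).

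An unnamed cluster of 345 cells, c33, held erythroid together with microglia genes. It was at 0.00909 to 4.48% of the cells in the WT and 0.479 to 0.785% in the KO libraries. Most of the WT cells came from 1 library, WT replicate 3, the only WT library in set 2. It held at most 0.00715% of the cells in the 5xFAD_WT and 0.0161% in the 5xFAD_KO libraries. Being unnamed, it was left out of the microglia-like sums, in which erythroid markers were higher in 5xFAD_WT than in WT. Replicates of one group differed in DAM-high cells, at 39.6% and 17.9% in 5xFAD_WT and 41.3%, 64.2% and 25.5% in 5xFAD_KO, and in both groups the library of set 2 had the lowest value.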
